A study of Mus musculus with 7 samples.

How the data were processed

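The samples were megakaryocyte-erythroid progenitors sorted from female C57BL/6 mice, a bone marrow population that gives rise to megakaryocytes and red blood cells. Per the labels, 3 samples came from mice lacking Ssb1 and Ssb2 and 4 from controls. Per the labels' protocols, total RNA was extracted with a column kit, treated with DNase and amplified to biotinylated cRNA. The arrays were MouseRef-8 v2.0 BeadArrays from Illumina read in a single colour, per the labels, on which probes attached to beads bind labelled cRNA. Per the submitters' processing notes, GenomeStudio was used, and its version and settings are not given in the sources used here.

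Several kinds of values were used. The authors deposited a table of probe signals, an intensity on a linear scale with no background subtracted and no normalization between arrays. Beside each signal the authors deposited a detection p-value, which sets the probe against the negative controls of its array. The authors also deposited a processed table on a log2 scale, which served as an alternative source of values. Set against the signals, the processed values matched quantile-normalized log2 signals that had been centred per probe. The median correlation per probe after centring was 0.999966, and the group differences correlated across probes at 0.999461 with probes not being independent replicates. The slope of the centred values was 0.966. The column medians of the processed table lay between 0.00164 and 0.00513. The direction of the processed values was that of the signals, and the baseline on which they were centred remains unknown.

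Signals were read and normalized with limma 3.58.1 in R 4.3.3. The function neqc estimated the background from the detection p-values, added an offset of 16, applied quantile normalization over the 7 arrays and took log2. Of 25697 probes, 23978 had 1 gene symbol in the annotation table, 0 had several and 1719 had none. Gene IDs of 23962 probes were found in the mouse gene table of assembly GRCm38.p6, and 0 symbols changed. No genome build is named for the arrays in the sources used here, so no coordinates are given. A probe was kept where its detection p was under 0.05 on at least 3 arrays, which left 10091 probes. Each gene was represented by its kept probe with the highest mean over the 7 arrays, giving 7547 genes. Among changed genes, 543 had several kept probes, 100 of these had another probe of opposite sign, and 18 had another probe called in the opposite direction. Histone and globin genes have near-identical copies, and what their probes bind is uncertain.

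Groups were compared with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p-values for genes are from this limma fit. The 24 gene lists, the rule for named genes, the design and all alternatives except the pair marked as added were fixed before the data were examined. The rule named the targeted genes and their partners, the 12 largest rises and the 12 largest falls among changed genes whose groups did not overlap, and up to 4 changed members of each list with the largest absolute change. Where no member changed, it took those with the smallest p. Genes with clone names were counted and not described, which affected 26 changed genes. Of the lists, 23 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether genes of a list move on balance in the same direction, stood beside it. The number of changed list members was also adjusted over the list alone. For a gene below background on every array of a group, no plain fold is given. Its lower bound sets the bright group's mean log2 value against the mean of the dim group, where each dim array takes the higher of the probe's own value and the lowest value among its detected probes. That lowest value is the detection floor of an array, to which the values of named genes detected on only some arrays of a group were also raised.

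The procedure was tested on simulated data for this comparison, with 200 of 7547 genes changed in 10 runs. It recovered 24.6% of genes shifted by 0.5 on the log2 scale, 76.3% of those shifted by 1 and 97.3% of those shifted by 2, and 4.85% of calls were false. A simulated list of 40 genes shifted by 0.5 was called in 10 of 10 runs, and an unshifted list in 0. With an estimated correlation the shifted list was called in 10 of 10 runs as well. The simulated genes were drawn independently, whereas the correlation estimated in the measured lists was 0.200 for interferon and 0.672 for mast cell markers. The simulation therefore does not test calls for lists whose genes vary together.

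The other settings fixed at that stage were no background correction, median scaling in place of quantile normalization, the processed table, no filter on dim probes, a filter at detection p under 0.01 on all 7 arrays, the mean of a gene's probes, a variance trend with robust fitting, array weights, the replicate number as a block, and leaving out each array. Added after seeing the data were the log2 mean signal of each array as a covariate and median scaling over the probes detected on all 7 arrays. The slide as a block was also intended and not run, because slides are not given in the sources used here. The number of arrays limits the precision: the median standard error of a log2 change was 0.151. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between these samples, which may be technical in part. Without background correction, signal shared by all probes stays in each value and shrinks log2 changes by construction. Figures were drawn with matplotlib 3.10.9.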

Results

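Gene expression was measured in megakaryocyte-erythroid progenitors of mice lacking both Ssb1 (Nabp2) and Ssb2 (Nabp1) and of control mice. These genes encode single-stranded DNA binding proteins that join Ints3 and Inip in the SOSS complex, which acts in the repair of DNA breaks. The progenitors had been sorted as lineage-low cells positive for c-Kit, negative for Sca-1 and low for CD34 and CD16/32. The double knockout group held 3 arrays and the control group 4. The mean signal of the knockout arrays was 660 ± 9.60 (SD, n = 3) against 515 ± 75.2 in controls (SD, n = 4), a difference with an exact two-sided permutation p of 0.0571, where the smallest p the design allows is 0.0286. Probes were detected at 42.4% ± 1.13 (SD, n = 3) on knockout arrays and 38.5% ± 1.58 (SD, n = 4) on control arrays, with the same exact permutation p of 0.0571. The knockout arrays were thus the brighter group, with control array 4 at 615 and control array 3 at 443 marking the range of the controls.

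The targeted genes were examined first. Nabp2 signal was 4.11-fold lower in the double knockout, a log2 change of -2.04 (SE 0.186, adjusted p = 0.000203), at 7.09 ± 0.0368 (SD, n = 3) against 9.13 ± 0.360 (SD, n = 4). The 3 knockout arrays read 7.13, 7.09 and 7.05, and the control arrays read 9.35, 9.17, 8.60 and 9.38, so each knockout array lay below every control array. The change was -1.42 without background correction, -1.39 under median scaling over all probes and -1.32 in the processed table. Another Nabp2 probe also fell, by 0.95 (SE 0.180, adjusted p over the kept probes = 0.00785). Where these probes lie relative to the deleted part of the gene is not given in the sources used here, and the remaining signal stayed above background on all 3 knockout arrays. The only Nabp1 probe was not above background on any of the 7 arrays and checks nothing. Ints3 differed by -0.09 (SE 0.138, adjusted p = 0.655), while another of its probes, lower in signal, was higher by 0.71 (adjusted p over the kept probes = 0.0460). Inip differed by -0.45 (SE 0.210, adjusted p = 0.142) and passed the threshold only without control array 2, at adjusted p = 0.0312.

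Of 7547 genes tested, 2051 changed between double knockout and control (27.2%), 1086 of them higher and 965 lower in the knockout. Counts of changed list members given below are to be read against these totals. The rises included genes of the interferon response and targets of p53, and the falls included B-lineage, globin and other red cell genes. A change of at least 2-fold was seen for 189 higher and 109 lower genes. Group values did not overlap for 2903 genes (38.5%, where chance gives 5.71%), among them 2000 of the changed genes. Correlations between arrays across genes, which are not independent replicates, were 0.987 to 0.995 within the knockout group, 0.983 to 0.990 within controls and 0.959 to 0.975 between groups. The first principal component held 58.2% of the variance, with the knockout arrays at 24.8 to 25.5 and the controls at -25.1 to -13.8. The count of changed genes was 1234 without knockout array 1 and 1145 without knockout array 3. Because the knockout arrays were also the brighter ones, adding array brightness as a covariate raised the median standard error from 0.151 to 0.259 and left 52 changed genes, 42 higher and 10 lower. The sign of the log2 change was kept for 99.9% of the changed genes, and the median ratio of the change with the covariate to that without it was 0.886. Scaling set the split of directions: 52.9% of changed genes were higher after quantile normalization, 97.01% after scaling each array to the same median over all probes (3768 higher, 116 lower) and 30.9% after scaling to the median of the probes detected on all arrays (810 higher, 1810 lower). These scalings moved the median log2 change of all genes to 0.52 and -0.14, against 0.0114 after quantile normalization. Rises and falls are therefore relative to the typical gene of these cells. Between 36.6% and 43.4% of probes were detected on each array, so the median over all probes was that of an undetected probe. Scaling to it held the background level equal and left the brighter signal of the knockout arrays in the changes.

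Of the 95 named genes that changed, 70 passed the threshold whichever array was left out. Without the filter on dim probes 82 of the 95 passed, with the replicate number as a block 79, and with the mean of a gene's probes 93. A variance trend with robust fitting kept 94. So did no background correction and the processed table, where Gp1bb lost its call (adjusted p = 0.0648 and 0.0592). With array brightness as a covariate, 17 of the 95 passed: Isg15, Oas2, Oasl2, Rsad2, Usp18, Gbp2, Gvin1, Irgm2, Tgtp1 and Zmat3 among the rises, and Nabp2, Vpreb3, Mzb1, Hbb-bt, Dmtn, Il31ra and Rgcc among the falls. Median scaling over all probes kept 67 of them, ended 26 calls, all of them falls, and turned the sign of Fancd2 and Uros. Median scaling over detected probes ended 10 calls (adjusted p 0.0522 to 0.233), that of Fancd2 and the rises of Cpa3, Fas, Gp1bb, Hsp90b1, Ints14, Jun, Lmo4, Nfkbie and Rrs1. The size of changes depends on the background correction: over the 95 genes the median ratio of the log2 change to that given here was 0.715 without it and 0.670 in the processed table.

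Genes of the interferon response rose together in the double knockout. Of 41 measured members, 36 rose and 0 fell, and the count was 36 when adjusted over the list alone. The median change was 3.03-fold (log2 1.60, or 1.52 with genes below background at their bounds), and it was smaller without background correction (log2 1.02) and in the processed table (log2 0.99). With array brightness as a covariate it was 1.55 on the log2 scale, and 19 members rose and 0 fell. Oasl2, an antiviral oligoadenylate synthetase-like protein, rose 19.0-fold (log2 4.25, SE 0.227, adjusted p = 2.21e-05), from 6.70 ± 0.283 (SD, n = 4) to 10.9 ± 0.461 (SD, n = 3). Its relative Oas2 was not above background on any control array and was at least 13.8-fold higher in the knockout (adjusted p = 2.06e-06). The ubiquitin-like modifier Isg15 rose 11.7-fold (log2 3.55, SE 0.173, adjusted p = 1.39e-05), and the antiviral enzyme Rsad2 11.4-fold (log2 3.52, SE 0.216, adjusted p = 2.61e-05). Usp18, the protease that removes Isg15 from proteins, rose by 3.11 on the log2 scale. The interferon-inducible GTPases Gbp2, Irgm2, Gvin1 and Tgtp1 rose by 3.20, 3.34, 3.61 and 3.61, with Tgtp1 detected on 1 of 4 control arrays and its rise 3.26 with values raised to each array's detection floor. All measured members had a median of 1.71, 1.44 and 1.60 relative to the control mean on the 3 knockout arrays and of -0.112 to 0.211 on the control arrays. Camera gave an adjusted p = 9.54e-25 for the list and an adjusted p = 0.197 with an estimated correlation.

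**Figure D1:**
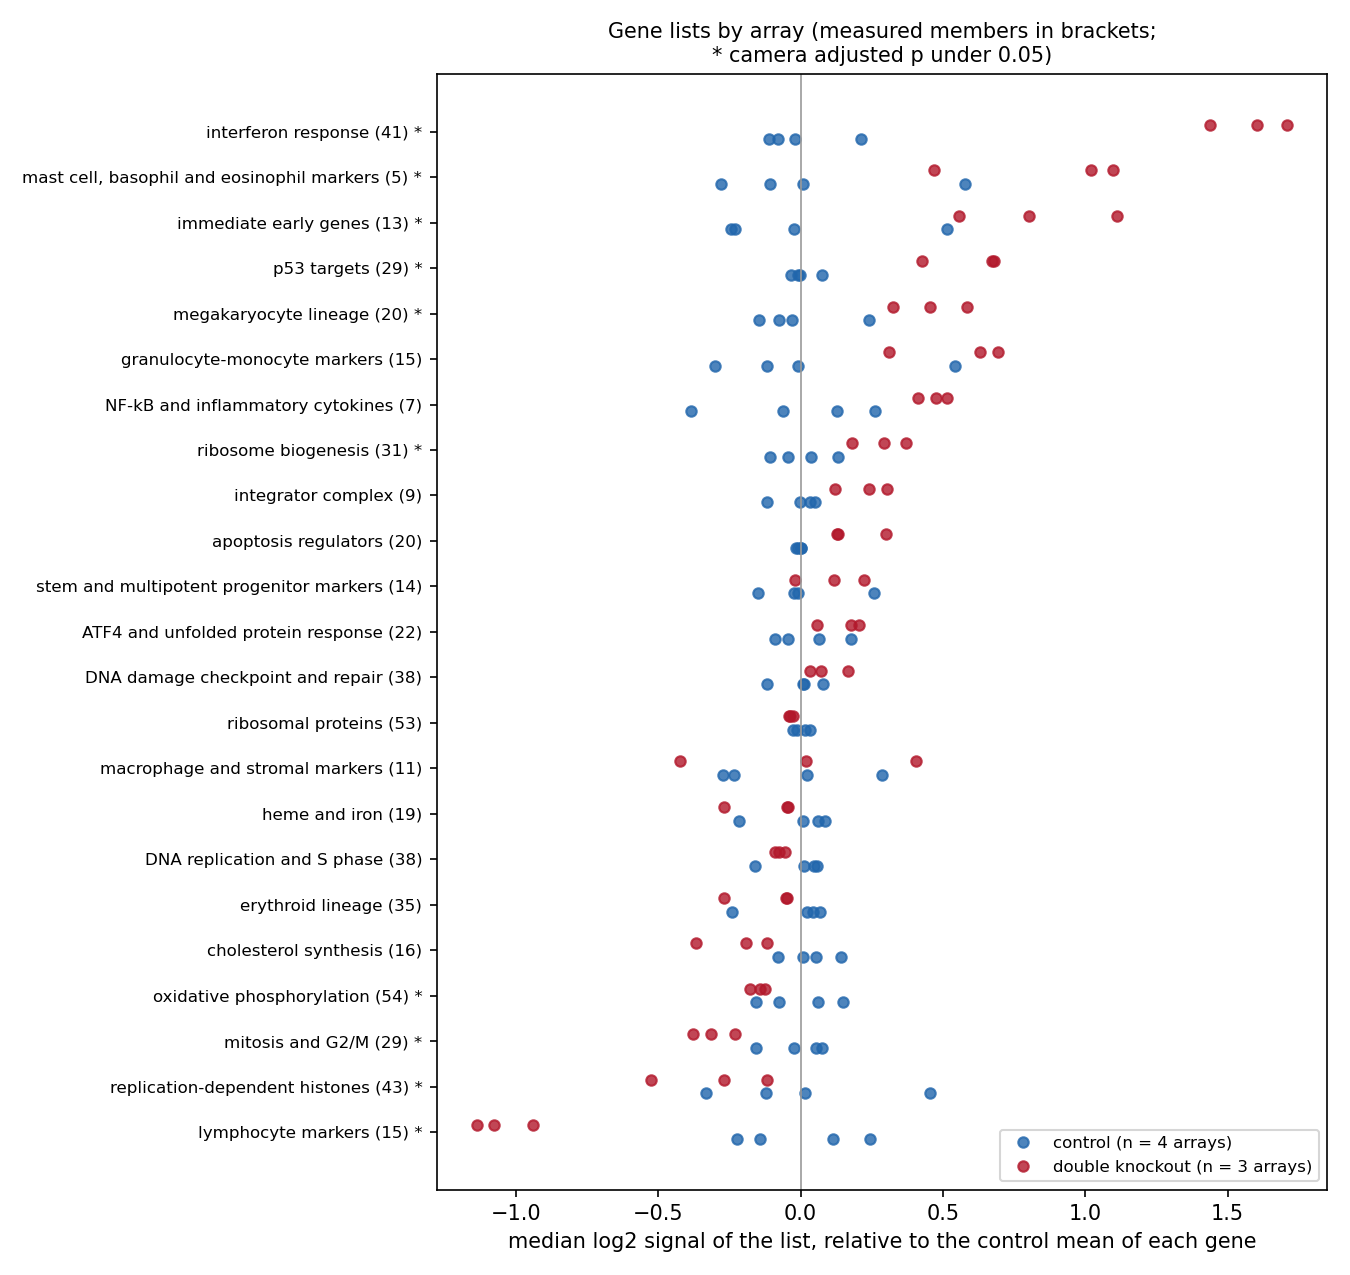
Median log2 signal of each gene list on each array, relative to the control mean of each gene (horizontal axis, log2 units); every dot is an array, blue for control (n = 4) and red for double knockout (n = 3), and an asterisk marks lists with a camera adjusted p under 0.05. The interferon list lies to the right on all 3 knockout arrays and the lymphocyte list to the left. For 12 of the 23 lists the groups do not overlap.

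Targets of p53, the transcription factor activated by DNA damage, were higher in the double knockout. Of 29 measured members, 19 rose and 1 fell, and adjusted over the list alone 21 rose and 1 fell. The median change was 0.59 on the log2 scale, or 0.56 with bounds. It was 0.27 both without background correction and in the processed table, and 1.07 under median scaling over all probes. There 24 rose and 0 fell, and over detected probes 14 and 1. With array brightness as a covariate the median was 0.62, and 1 member rose and 0 fell. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by a log2 change of 2.79 (SE 0.326, adjusted p = 0.000820), or 5.95-fold with values raised to the detection floor, and was detected on 3 of 4 control arrays. Zmat3, an RNA-binding protein induced by p53, rose by 2.32 on the log2 scale (SE 0.161, adjusted p = 5.68e-05), and the stress-induced mTOR inhibitor Ddit4 rose 4.44-fold (log2 2.15, SE 0.253, adjusted p = 0.000850). Ccng1, which encodes cyclin G1, rose by 1.15, although another of its probes had the opposite sign. The member that fell was Fbxw7, a subunit of a ubiquitin ligase, at -0.52, chosen here after its value was seen. Camera gave an adjusted p = 2.11e-06, and an adjusted p = 0.229 with an estimated correlation. Without knockout array 2, 12 members rose.

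Among 20 measured regulators of cell death, 7 rose and 0 fell, with 7 also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.103, and 0.464 with an estimated correlation). Under median scaling 14 rose and 0 fell over all probes, and 5 and 1 over detected probes. Those that moved act in different ways. Mlkl, the effector of necroptosis, rose by 0.89, the p53-induced killer protein Bbc3 by 0.89, and the survival protein Mcl1 by 0.70. The death receptor Fas was below background on every control array and at least 1.21-fold higher in the knockout (adjusted p = 0.00890), a call lost under median scaling over detected probes (adjusted p = 0.233). Of 38 genes of the DNA damage checkpoint and repair, 1 rose and 2 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.616). These counts depend on scaling: 23 rose and 0 fell under median scaling over all probes, and 1 rose and 8 fell under median scaling over detected probes. Rpa2, a subunit of the other major single-stranded DNA binding complex, was 1.99-fold lower (log2 -0.996, SE 0.183, adjusted p = 0.00552). The DNA ligase Lig3 rose by 0.62, a call lost without knockout array 1 or 3 (adjusted p = 0.0574 and 0.0627). Fancd2, of the Fanconi anaemia pathway, was at -0.36 (adjusted p = 0.0466). Its call was lost without any of the 7 arrays (adjusted p 0.0533 to 0.120), and its change was 0.32 under median scaling over all probes.

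Genes of mitosis were lower in the double knockout: of 29 measured, 10 fell and 0 rose, and adjusted over the list alone 12 fell and 1 rose. Cdk1, the kinase that drives entry into mitosis, was at -0.94 (SE 0.204, adjusted p = 0.0108), the chromosomal passenger protein Cdca8 at -0.93 (SE 0.190, adjusted p = 0.00847), the phosphatase Cdc25c at -0.82 (SE 0.133, adjusted p = 0.00334) and Cdca3 at -0.77 (SE 0.120, adjusted p = 0.00284). The list's median was -0.32, and under median scaling over all probes it was 0.25, or -0.27 relative to the median gene, with 8 members called higher and 0 lower there, against 0 and 14 over detected probes. It was -0.21 without background correction and -0.20 in the processed table. With array brightness as a covariate it was -0.36, and 0 members were called. Camera gave an adjusted p = 0.00149, and an adjusted p = 0.464 with an estimated correlation. Of 38 genes of DNA replication, 9 fell and 1 rose, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.148). Those that fell included the transcription factor E2f2 at -1.07, the thymidine kinase Tk1 at -0.83, cyclin E1 (Ccne1) at -0.74 and the thymidylate synthase Tyms at -0.69, for which another probe had the opposite sign. The member that rose, Mcm2 at 0.42, was chosen after its value was seen. The number that fell was 5 without knockout array 1 and 4 without knockout array 3, and the list's median of -0.11 was 0.43 under median scaling over all probes, or -0.0922 relative to the median gene, and -0.23 over detected probes. In these scalings 14 rose and 0 fell, and 0 rose and 13 fell. With array brightness as a covariate 0 members of the DNA replication list were called. The groups overlapped for the DNA replication list, with control array 1 at -0.162 and the knockout arrays at -0.0896 to -0.0563. Of 43 replication-dependent histone genes, whose probes may bind near-identical copies, 7 fell and 0 rose, with 5 falling when adjusted over the list alone. H2ac8 was at -1.31, H2ac21 at -0.91, H2ac11 at -0.83 and H1f5 at -0.77. The histone list passed camera (adjusted p = 0.00342) with a median of -0.32, but not with an estimated correlation (adjusted p = 0.560), by fry (adjusted p = 0.177) or with array brightness as a covariate (adjusted p = 0.0979). Its median under median scaling over all probes was 0.16, or -0.36 relative to the median gene. It was -0.15 without control array 1, which stood at 0.453 against 0.0165 or less on the other controls, and -0.20 without knockout array 2. It was -0.20 in the processed table and -0.50 under median scaling over detected probes, where 0 rose and 13 fell, against 5 and 3 over all probes. With array brightness as a covariate it was -0.18, and 0 rose and 0 fell. The groups overlapped for this list. The number of histone genes that fell was 3 without knockout array 3 and 4 without knockout array 2. H2ac8 lost its call without knockout array 3 (adjusted p = 0.0655), and H1f5 without any array except control array 4 (adjusted p 0.0665 to 0.153).

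Several red cell genes fell, while the erythroid list as a whole did not pass the test. Of 35 measured erythroid genes, 6 fell and 2 rose, also adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.129). Slc4a1, the anion exchanger band 3 of the red cell membrane, was lower by a log2 change of -2.69 (SE 0.368, adjusted p = 0.00160), or 6.04-fold with values raised to the detection floor, and was detected on 1 of 3 knockout arrays. The globin genes Hbb-bt and Hba-a1, which have near-identical copies, were 7.26-fold and 2.49-fold lower (log2 -2.86, SE 0.246, adjusted p = 0.000160, and log2 -1.31, SE 0.237, adjusted p = 0.00504). The blood group protein Rhd was at -1.11 and the adhesion molecule Icam4 at -0.98, and Dmtn, a protein of the red cell membrane skeleton outside the list, was 5.19-fold lower (log2 -2.38, SE 0.168, adjusted p = 6.08e-05). The transcription factors Gata1 and Klf1 were at -0.48 and -0.32 (adjusted p = 0.0521 and 0.0522), named after their values were seen, as were the members that rose, Ces2g by 0.80 and the transcription factor Nfe2 by 0.61. The erythroid list passed camera without knockout array 3 (adjusted p = 0.0469) and without control array 1 (adjusted p = 0.0382), where 10 members fell. Without knockout array 2 its median was -0.0384 (adjusted p = 0.302) and without control array 2 it was -0.0833. With array brightness as a covariate it was -0.0395. Its median was 0.38 under median scaling over all probes, or -0.14 relative to the median gene, where camera gave an adjusted p = 0.00556 and 10 rose and 3 fell. Over detected probes 1 rose and 12 fell. Of 19 genes of heme synthesis and iron, 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.156). The iron regulatory protein Aco1 rose by 1.09 and the heme synthesis enzymes Ppox, Cpox and Uros were at -0.68, -0.83 and -0.61. Cpox lost its call without any array except knockout array 1 or control array 1 (adjusted p 0.0615 to 0.140), as did Uros (adjusted p 0.0515 to 0.0923), whose change under median scaling over all probes was 0.0424. The number of heme genes that fell was 2 without knockout array 2 or 3 or control array 2, 3 or 4, and 3 without knockout array 1. Under median scaling 7 rose and 0 fell over all probes, and 1 and 10 over detected probes. For the erythroid and the heme list the groups overlapped. The median of the heme list, -0.0817, was 0.28 under median scaling over all probes, or -0.24 relative to the median gene, while it was -0.0232 without knockout array 2 and -0.137 without control array 4. It was -0.38 over detected probes, -0.0271 with array brightness as a covariate and -0.132 without knockout array 1.

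Megakaryocyte genes were higher in the double knockout: 8 of 20 measured rose and 0 fell, also adjusted over the list alone, with a median of 0.51. It was 0.21 without background correction, 0.20 in the processed table and 0.27 with array brightness as a covariate, where 0 members were called. Under median scaling it was 0.94 over all probes, where 15 rose and 0 fell, and 0.28 over detected probes, where 5 rose and 1 fell. Control array 1 stood at 0.238, above the other controls at -0.0300 or less and near knockout array 1 at 0.324. Itga2b, the platelet integrin subunit CD41, rose 3.96-fold (log2 1.99, SE 0.258, adjusted p = 0.00133), from 6.58 ± 0.544 (SD, n = 4) to 8.57 ± 0.106 (SD, n = 3). The homeobox factor Meis1 rose by 1.26, Nrgn by 0.997 and the platelet glycoprotein Gp1bb by 0.86, the last detected on 1 of 4 control arrays and at 0.54 with values raised to the detection floor. Camera gave an adjusted p = 0.0120, and an adjusted p = 0.464 with an estimated correlation, 0.0606 by fry, 0.0691 with the stricter detection filter and 0.0979 with array brightness as a covariate. Without control array 3, 5 members rose. Meis1 lost its call without knockout array 1 or 2 or control array 2 or 3 (adjusted p 0.0510 to 0.0825), and Gp1bb without any array except knockout array 1 or control array 1 (adjusted p 0.0558 to 0.145). Among 14 markers of stem and multipotent progenitors, 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.463). Under median scaling 7 rose and 0 fell over all probes, and 3 rose and 4 fell over detected probes. The groups overlapped for this list. The early growth response factor Egr1 rose 5.35-fold (log2 2.42, SE 0.295, adjusted p = 0.00104), Gata2, a transcription factor of early blood progenitors, 3.04-fold (log2 1.60, SE 0.187, adjusted p = 0.000812), and the TGF-beta co-receptor Eng by 0.70. Mllt3 was at -0.67 and lost its call without knockout array 2 or 3 or control array 1, 2 or 3 (adjusted p 0.0515 to 0.0831). The other member that fell was Mecom, at -0.51, named after its value was seen, and without knockout array 3 the number that fell was 0, with 1 without knockout array 2 or control array 2 or 3.

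**Figure D2:**
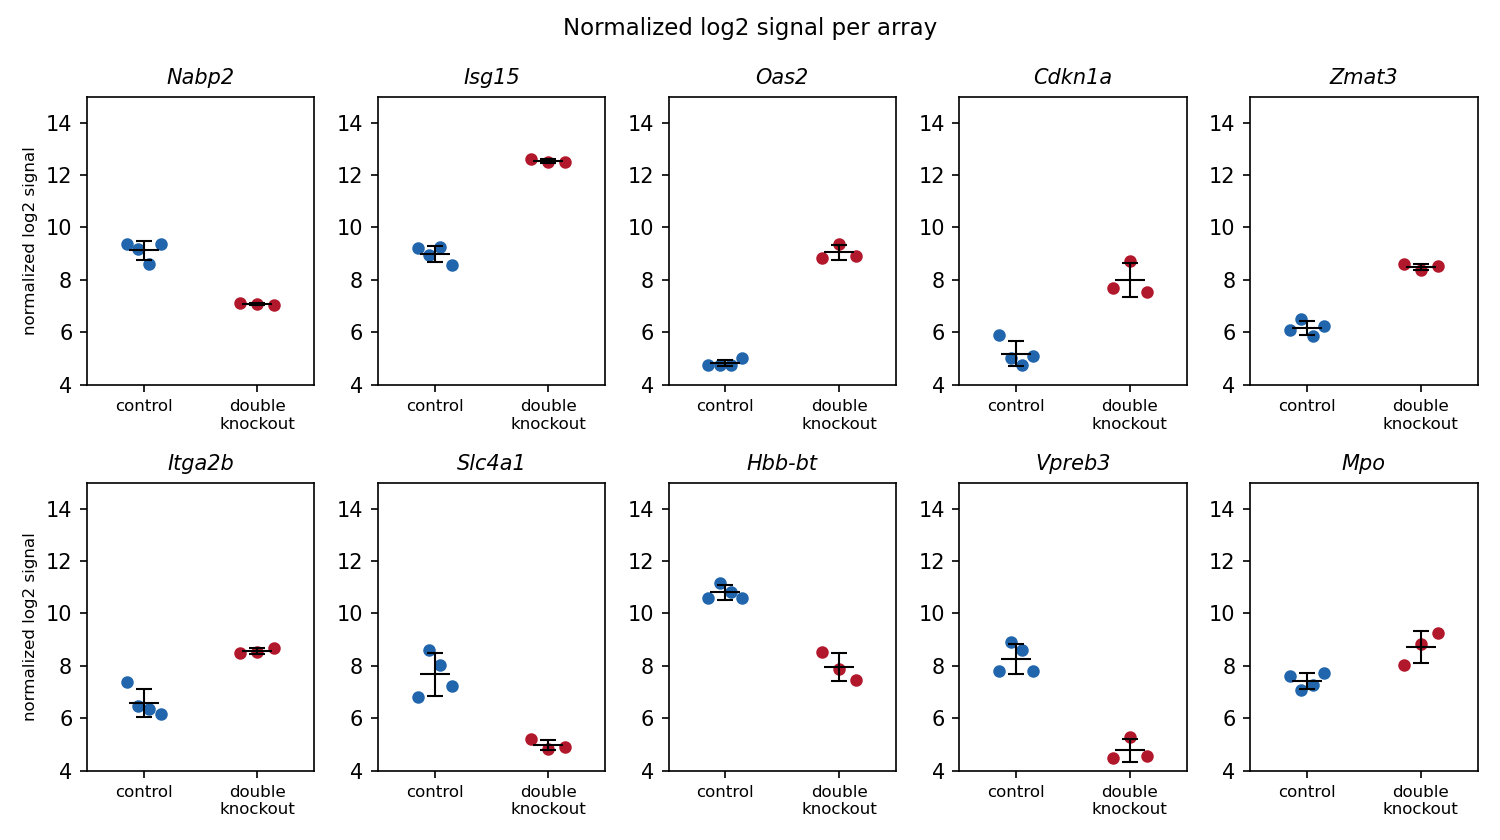
Normalized log2 signal (vertical axis) of 10 genes on each array, with control arrays in blue (n = 4) and double knockout arrays in red (n = 3); lines show the mean and SD of each group. In every panel the groups do not overlap, with Nabp2, Slc4a1, Hbb-bt and Vpreb3 lower and the other genes higher in the double knockout, and Oas2 not above background on control arrays.

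Markers of other blood cells also differed between the sorted populations. Of 15 measured lymphocyte markers, 10 fell and 0 rose, or 12 and 1 adjusted over the list alone, with a median of -0.98. It was -0.32 both without background correction and in the processed table, with 7 falling in each, and -0.49 with array brightness as a covariate, where 1 fell. Genes of the B lineage led. Vpreb3 and the pre-B cell receptor component Vpreb1 were lower by log2 changes of -3.50 (SE 0.309, adjusted p = 0.000183) and -2.78 (SE 0.362, adjusted p = 0.00133). Vpreb3 was detected on 1 of 3 knockout arrays, and with values raised to the detection floor it was 9.17-fold lower. The B cell receptor subunit Cd79b was 4.35-fold lower (log2 -2.12, SE 0.289, adjusted p = 0.00156). The chemokine Ccl5 was not above background on any knockout array and was at least 4.02-fold lower (adjusted p = 0.00699). Cd52 of lymphocyte membranes and Mzb1 of B cells, the latter outside the list and detected on 1 of 3 knockout arrays, were at -1.96 and -2.73, or -2.66 for Mzb1 with values raised to the detection floor. By camera the lymphocyte list had an adjusted p = 2.90e-05, and an adjusted p = 0.464 with an estimated correlation. Of 5 measured markers of mast cells, basophils and eosinophils, 4 rose, also adjusted over the list alone, with a median of 0.94. It was 0.54 without background correction and 0.53 both in the processed table and with array brightness as a covariate, and 2 rose under median scaling over detected probes. The groups overlapped for this list, with control array 1 at 0.578 and knockout array 2 at 0.469 relative to the control mean. The histidine decarboxylase Hdc rose 3.01-fold (log2 1.59, SE 0.221, adjusted p = 0.00175), Csrp3 by 1.09, the mast cell protease Cpa3 by 0.94 and the transcriptional regulator Lmo4 by 0.57. With camera the list had an adjusted p = 0.0358, and an adjusted p = 0.464 with an estimated correlation, 0.0605 by fry, 0.180 without the detection filter and 0.0674 with array brightness as a covariate. It was 0.0667 without control array 2 and 0.0899 without control array 4. Cpa3 and Lmo4 lost their calls without knockout array 1 or 3 or control array 2, 3 or 4 (adjusted p 0.0612 to 0.134 for Cpa3 and 0.0529 to 0.0980 for Lmo4), leaving 2 markers that rose.

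Of 15 granulocyte-monocyte markers, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.103). Here too the groups overlapped, with control array 1 at 0.542 and knockout array 1 at 0.310. Under median scaling 9 rose and 1 fell over all probes, and 4 and 3 over detected probes. Plac8 rose 3.37-fold (log2 1.75, SE 0.256, adjusted p = 0.00222), the granule protease Ctsg by 1.53, the myeloperoxidase Mpo by 1.30 and the calcium-binding protein S100a8 by 1.45. Lyz2, the lysozyme of macrophages and granulocytes, was at -1.14 (adjusted p = 0.00385), named after its value was seen. S100a8 lost its call without knockout array 2 or 3 or control array 4 (adjusted p 0.0651 to 0.100). The list passed camera without knockout array 1 (adjusted p = 0.0207), without control array 1 (adjusted p = 0.0220) and with the stricter detection filter (adjusted p = 0.00574). Of 11 markers of macrophages and stromal cells, 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.588): the apolipoprotein Apoe was at -1.10, a call lost without knockout array 1 (adjusted p = 0.0567). Under median scaling over all probes 4 of these markers rose and 0 fell.

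Genes of ribosome biogenesis were higher in the double knockout, with 11 of 31 rising and 1 falling, or 12 and 1 adjusted over the list alone, and a median of 0.27, or 0.0723 under median scaling over detected probes, where 4 rose and 2 fell, against 24 and 0 over all probes. The nucleolar proteins Rrp1, Nop2 and Rrs1 rose by 0.91, 0.74 and 0.62, and the acetyltransferase Nat10 was at -0.83 (SE 0.168, adjusted p = 0.00835). In the camera test the list had an adjusted p = 0.00444, and an adjusted p = 0.464 with an estimated correlation, 0.0573 with array brightness as a covariate, 0.153 under median scaling over all probes and 0.0700 under median scaling over detected probes. The number that rose was 4, 7 and 5 without knockout arrays 1, 2 and 3 and 7 without control array 3. Rrp1 lost its call without any knockout array or control array 3 (adjusted p 0.0553 to 0.0951), and Rrs1 without knockout array 1 or 3 (adjusted p = 0.0645 and 0.0717). Of 53 ribosomal protein genes, 2 fell and 0 rose, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.284): Rpl14 was at -0.67 and Rpl13a at -0.38, the latter lost without any array except knockout array 2 (adjusted p 0.0579 to 0.149). This list passed camera under median scaling over all probes (adjusted p = 3.11e-05) and over detected probes (adjusted p = 1.28e-05), where its median was -0.64, or -0.50 relative to the median gene, and 33 fell and 0 rose, against 0 and 4 over all probes. Those scalings differ only by a constant per array and give the same list medians relative to the median gene. List results under them are therefore not independent.

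Of 54 genes of oxidative phosphorylation, 13 fell and 1 rose, also adjusted over the list alone, with a median of -0.22. The ATP synthase subunits Atp5o and Atp5e were at -1.03 and -0.87, the cytochrome Cyc1 at -0.96 (SE 0.153, adjusted p = 0.00306) and the cytochrome oxidase subunit Cox7a2 at -0.70. Atp5j rose by 0.53, named after its value was seen. The camera test gave an adjusted p = 0.0178, and an adjusted p = 0.560 with an estimated correlation, 0.0945 by fry and 0.196 with array brightness as a covariate. It was 0.0704 without control array 1 and 0.0723 without control array 2, and 5, 7, 5 and 8 members fell without knockout arrays 1, 2 and 3 and control array 3. Under median scaling over all probes the median of the list was 0.16, or -0.36 relative to the median gene. It was -0.14 without knockout array 2 or control array 1 and -0.11 with array brightness as a covariate. Under median scaling 7 rose and 1 fell over all probes, and 0 and 27 over detected probes with a median of -0.50. The groups overlapped for this list. Atp5o lost its call without any knockout array or control array 2 (adjusted p 0.0518 to 0.0921), and Cox7a2 without knockout array 1 or 3 (adjusted p = 0.0795 and 0.0811). Of 16 genes of cholesterol synthesis, 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.103): Pmvk at -1.02, Fdps at -0.79 and Ebp at -0.76. This list passed camera without knockout array 2 (adjusted p = 0.0499) and with array brightness as a covariate (adjusted p = 0.0339), and its median of -0.15 was 0.37 under median scaling over all probes, or -0.15 relative to the median gene. It was -0.40 with array brightness and -0.0889 without control array 4. Under median scaling 6 rose and 0 fell over all probes, and 0 and 5 over detected probes. Without control array 3, 5 of them fell. Fdps lost its call without knockout array 1 or 3 (adjusted p = 0.0643 and 0.0655). Of 22 genes of the ATF4 and unfolded protein responses, 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.148, but 0.0106 without the detection filter). The endoplasmic reticulum proteins Pdia4 and Hsp90b1 rose by 1.07 and 0.65 and the serine synthesis enzyme Psat1 by 0.67, while Atf4 itself was at -0.74. Psat1 lost its call without knockout array 1 or 3 or control array 1 or 3 (adjusted p 0.0599 to 0.105), and Atf4 without knockout array 2 (adjusted p = 0.0503). The number that rose was 4 without knockout array 1 or control array 3, 17 under median scaling over all probes and 3 over detected probes.

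Immediate early genes, which respond within minutes to signals and stress, were higher in the double knockout. Of 13 measured, 7 rose and 0 fell, or 9 and 0 adjusted over the list alone, with a median of 0.84, or 0.70 with bounds. It was 0.31 without background correction and 0.28 in the processed table. Under median scaling it was 1.18 over all probes, where 11 rose and 0 fell, and 0.52 over detected probes, where 4 rose and 1 fell. Control array 1 stood at 0.515, apart from the other controls at -0.0249 or less and near knockout array 2 at 0.557. Beside Egr1, the factor Fos rose 3.61-fold (log2 1.85, SE 0.401, adjusted p = 0.0106), Junb 2.17-fold (log2 1.12, SE 0.194, adjusted p = 0.00440) and Jun, detected on 2 of 4 control arrays, by 1.02, or 0.92 with values raised to the detection floor. Jun lost its call without any array except control array 1 (adjusted p 0.0652 to 0.125). By camera the list had an adjusted p = 0.00507, and an adjusted p = 0.464 with an estimated correlation and 0.0605 by fry, and 4 members rose without knockout array 3. Of 7 measured genes of NF-kB and inflammatory cytokines, 3 rose and 1, Ccl5, fell, also adjusted over the list alone (camera adjusted p = 0.148). Under median scaling 6 rose and 1 fell over all probes, and 2 and 1 over detected probes. The feedback inhibitor Tnfaip3 rose by 0.96, or 0.74 with values raised to the detection floor, with detection on 2 of 4 control arrays, and the inflammatory caspase Casp1 by 0.74, a call lost without knockout array 1 (adjusted p = 0.0700). The inhibitor Nfkbie was below background on every control array and at least 1.47-fold higher in the knockout (adjusted p = 0.00259), a call lost under median scaling over detected probes (adjusted p = 0.0827). Of 9 genes of the integrator complex, which processes small nuclear RNAs and also contains Ints3, 2 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.174, and 0.0480 without the detection filter). Under median scaling 8 rose over all probes and 1 over detected probes. Ints5 rose by 0.58 and Ints14 by 0.44. Ints5 lost its call without any array except knockout array 2 or control array 2 (adjusted p 0.0519 to 0.104), and Ints14 without knockout array 2 or 3 or control array 2 or 3 (adjusted p 0.0510 to 0.0770).

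Outside these groups, the largest rise was that of Trnp1, a nuclear protein that controls the proliferation of neural progenitors. It was below background on every control array and at least 53.5-fold higher in the knockout (adjusted p = 0.000995), at 12.1, 8.45 and 12.4 on the 3 knockout arrays. The fitted log2 change moved from 6.49 to 7.72 without knockout array 2, 5.85 without knockout array 1 and 5.74 without knockout array 3. Acot1, an acyl-CoA thioesterase, rose by a log2 change of 3.05 (SE 0.446, adjusted p = 0.00222), or 7.13-fold with values raised to the detection floor, and was detected on 2 of 4 control arrays. The cytokine receptor subunit Il31ra was 4.19-fold lower (log2 -2.07, SE 0.201, adjusted p = 0.000297), and Rgcc, a regulator of the cell cycle, 3.63-fold lower (log2 -1.86, SE 0.173, adjusted p = 0.000222).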

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

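No test in this part was chosen after its result was seen. Control values of 123 quantities were screened for an array lying far from the other controls, and 3 did (2.44%), where chance gives about 5%. Control array 4 read 4.997 for Oas2 while the other controls lay at 4.74 to 4.76, and Oas2 was not detected above background on any of the 4. Control array 1 read 9.94 for Csrp3 against 8.86 to 8.92 in the other controls, and the rise of Csrp3 in the knockout kept its call without this array. The median of the erythroid list on control array 1 was -0.242 relative to the control mean of each gene, against 0.0229 or more on the other controls.

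Probes with no gene symbol in the annotation table stood outside the comparisons above. Of 632 such probes that were detected, 189 changed, 103 higher and 86 lower in the double knockout, with the largest rise in probe ILMN_2725927 (log2 3.42, adjusted p = 6.93e-05 over the kept probes).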

How the results depend on the processing

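The fits with array brightness as a covariate and with median scaling over the probes detected on all 7 arrays were chosen after the results were seen. Nabp2 kept its fall under all 18 alternative settings, at -2.22 to -1.95 without each array. Changed genes numbered 1145 to 1921 without each array (626 to 1019 higher and 519 to 902 lower), with the fewest without knockout array 3 and 1234 (692 higher, 542 lower) without knockout array 1, where fewer arrays remain. They numbered 3884 (3768 higher, 116 lower) under median scaling over all probes, 1810 were lower under median scaling over detected probes, and 52 (42 higher, 10 lower) remained with array brightness, which is partly confounded with the group. With the replicate number as a block they numbered 1355 (631 lower), but the labels do not say that the numbers pair the samples. Deviations of samples sharing a number correlated at -0.169, -0.0160 and 0.0277, and not every sample correlated best with its own number. No large effect shared by number was thus seen, which does not exclude a pairing. The share of variance on the first component was 58.2%, 56.5% to 63.5% without each array, 64.5% without background correction, 75.7% under median scaling, 64.4% in the processed table, 50.7% without a detection filter, 63.7% with the stricter filter and 62.3% under scaling over detected probes. Estimated correlation ended the call of all 10 lists that passed camera, at adjusted p = 0.197 for interferon, 0.229 for p53, 0.464 for mitosis, megakaryocyte, mast cell, lymphocyte, ribosome biogenesis and immediate early genes, and 0.560 for histones and oxidative phosphorylation. By fry, adjusted p was 0.177 for histones, 0.0606 for megakaryocyte, 0.0605 for mast cell and immediate early genes and 0.0945 for oxidative phosphorylation, while ATF4 (0.0338), apoptosis (0.00405) and NF-kB (0.0489) passed. With array brightness it was 0.0979 for histones and megakaryocyte, 0.0674 for mast cell, 0.0573 for ribosome biogenesis and 0.196 for oxidative phosphorylation, and cholesterol passed at 0.0339. Under median scaling over all probes, erythroid (0.00556), granulocyte-monocyte (0.0182) and ribosomal protein genes (3.11e-05) passed and ribosome biogenesis did not (0.153). Under scaling over detected probes, erythroid and apoptosis (both 0.0352) and ribosomal proteins (1.28e-05) passed and ribosome biogenesis did not (0.0700). The median scalings differ only by a constant per array, so their list results are not independent. With the stricter filter megakaryocyte genes had 0.0691 and granulocyte-monocyte markers 0.00574. Without the filter mast cell markers had 0.180, and integrator (0.0480), ATF4 (0.0106) and apoptosis genes (0.0242) passed. With the mean of a gene's probes apoptosis genes passed at 0.0279. Without each array, adjusted p ran from 0.0382 to 0.302 for erythroid, 0.0207 to 0.155 for granulocyte-monocyte, 0.00377 to 0.0899 for mast cell, 0.00379 to 0.0723 for oxidative phosphorylation and 0.0499 to 0.180 for cholesterol genes. No other list changed sides under any setting run. Under median scaling over all probes, where the typical gene shifts by 0.52, Fancd2 was at 0.32 (adjusted p = 0.244) and Uros at 0.0424 (adjusted p = 0.896). Except where stated, the cause was not tested. No fit with slides was run. Signal over background limits 115 of the changed genes to a bound on their fold.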

Other observations

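The gene lists in this part were written after the first fit was seen, when values of some of their members were already known, and the tests for lymphocytes, for macrophages, for 1 deviating array and for a linear brightness trend were chosen after the result was seen. Genes of antigen presentation on MHC class I were higher in part: of the 13 measured members not seen before and not held by the fixed lists, 6 rose and 0 fell, with a median of 0.48 (camera p = 0.00118, and p = 0.160 with an estimated correlation). The class I molecules H2-K1 and H2-D1 did not pass the threshold (log2 0.26 and -0.06, adjusted p = 0.283 and 0.771). The transactivator Nlrc5, which had been seen before the list was written, rose 3.98-fold (log2 1.99, SE 0.180, adjusted p = 0.000199), the class I molecule H2-T23 1.83-fold and the shared light chain B2m 1.55-fold. Interferon-inducible GTPases, of which all but Gbp7 were held by the interferon list or had been seen before, rose in 9 of 9 measured members, which adds little to the interferon result. Of 14 measured B-lineage genes 10 fell (median -1.26), against 1 of 6 markers of T and NK cells (median 0.0597). Most of these B-lineage genes had been seen before: of the 3 that had not, 1 fell, and the list adds little to the lymphocyte result. The difference between the B-lineage and the T and NK lists was not tested.

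Among the largest rises outside the fixed lists were Tsc22d3 (4.75-fold, adjusted p = 0.000320) and Per1 (4.19-fold, adjusted p = 0.000551), both induced by glucocorticoids. A hypothesis was that other glucocorticoid-induced genes rose too. Of the 14 measured members not seen before and not held by the fixed lists, 5 rose and 0 fell, with a median of 0.48 (camera p = 0.00181, and p = 0.0508 with an estimated correlation). Fkbp5 rose 3.36-fold, and Cxcr4, Txnip, Gadd45g and Tgfbr2 by 0.85, 0.82, 0.79 and 0.68 on the log2 scale. The other members did not pass the threshold, among them Sgk1, Mt1, Klf9, Angptl4 and Irs2 at 0.46, 0.29, 0.18, -0.13 and -0.82 (adjusted p 0.0781 to 0.560). The rise of part of the list goes with a glucocorticoid-induced program in the knockout cells, but does not show one. Several of the genes that rose also answer other stress signals, and the list was run under no other scaling or brightness fit.

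For the number of changed genes, the 7 arrays were split into 3 and 4 in all 35 ways. Only 1 split, the real comparison with 2051, gave as many, and the highest of the others gave 4. With 35 splits the smallest share possible is 0.0286. Each other split mixes knockout and control arrays, which raises the spread within its groups and lowers its count. The splits thus show that the arrays separate by group and exclude no cause of that separation. Brighter knockout arrays stay open: the fit with array brightness left 52 changed genes, as the median standard error rose from 0.151 to 0.259 while the changes kept a median ratio of 0.886, and the shift of changed genes in control array 4, 0.133 of their knockout shift, rests on 1 array and on genes called partly for a small spread among controls. Passenger DNA of another strain beside the targeted alleles was tested on up to 50 measured neighbours on each side of Nabp1 and Nabp2. Of 166 neighbours 24.1% changed against 27.2% of other genes (odds ratio 0.848, 95% interval 0.577 to 1.22, Fisher's exact two-sided p = 0.427), so no excess was seen. A few affected genes close to the loci could not show as an excess in so wide a window, so passenger effects on single genes stay open. Stat2 of the interferon list and Mdm2 of the p53 list were among the changed neighbours.

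For the rise of interferon genes, a linear brightness trend is argued against as the whole cause: over all 41 measured members the mean rise was 1.72 (SE 0.0929) without array brightness in the fit and 1.81 (SE 0.165, 95% interval 1.35 to 2.27) with it, whereas the shift in control array 4 (0.0311 of the knockout shift) rests on 1 array and decides nothing. A single deviating array is argued against by the lowest knockout array, at a median of 1.44 over all members. More B-lineage cells in the knockout sort are argued against by the lymphocyte list, in which B-lineage genes led. The highest median of that list on a knockout array was -0.942. Markers of T and NK cells had a median of 0.0597, and the highest lymphocyte marker on knockout array 2 stood at 1.40. The list therefore does not decide on T or NK cells. More macrophages, which the lineage-low gate should also exclude, are argued against as the whole source. No member of the macrophage and stromal list exceeded 1.09 on any knockout array, below the interferon median of 1.44. The list's median was 0.0195, -0.424 and 0.404 on the 3 knockout arrays. A fold depends on the control level of each gene, so a small share of macrophages stays open. Granulocytes or monocytes, which a gate low for lineage markers and CD16/32 should in part exclude, could bring some of the signal. The median rise of 7 of their abundant genes was 0.994. This lay between the bounds set for either outcome, just under the bound of 1 set for such cells. Ctsg, S100a8 and Mpo rose by 1.53, 1.45 and 1.30. S100a9, Elane and Prtn3 were at 0.99, 0.50 and 0.35 and did not pass the threshold, while Lyz2 was at -1.14. Mast cells were not tested by these genes, and an effect of losing Ssb1 and Ssb2 within the progenitors stays open beside these.

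For the fall of lymphocyte markers, the mean over all 15 measured members was -1.22 (SE 0.206) without array brightness in the fit and -0.73 (SE 0.240, 95% interval -1.40 to -0.0667) with it, so a linear brightness trend is narrowly argued against as the whole cause, while a part stays open. The shift in control array 4, 0.273 of the knockout shift, rests on 1 array and decides nothing. Fewer lymphoid cells in the knockout sort may be the source, although a lineage-low, c-Kit-positive gate should exclude most of them in both groups. The 14 B-lineage genes varied together over the 4 controls, with a mean pairwise correlation of 0.358 at the 99.96 percentile of 10000 random sets (median -0.0147, 95th percentile 0.123). The random sets were matched on mean level only, and genes regulated together within cells would also vary together. This result therefore does not tell fewer cells from lower expression. Lower expression of these genes within the progenitors was not tested separately.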
